A study of Mus musculus with 8 samples.

How the data were processed

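The series measured total RNA from mouse retina on Affymetrix 3' expression arrays, with 1 array per sample. Retinas were taken at postnatal day 40 from mice of the strain labelled BALB/c AJ, after the retinal pigment epithelium (RPE) had been removed, per the labels' protocols. The genotype labels put 3 arrays in a wild-type group, 2 in a group heterozygous for an Nxnl1 null allele and 3 in a homozygous null group. The series' design text speaks of 9 samples, and the ninth was not analysed here. Nothing in the labels says that the arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

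The deposited table holds log2 expression values, 1 per probe set and array, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, makes the distributions of all arrays alike by quantile normalization and summarises the probes of each probe set on the log2 scale. Its version and settings are not given in the sources used here, nor whether the ninth sample entered the normalization. Quantile normalization removes any difference between arrays in total signal, so each change is relative to the bulk of the transcripts. The values ran from 2.50 to 14.57, and the array medians from 6.11 to 6.21. The number of arrays limits the precision, and no detection calls were used here, so transcripts near the lower end of the scale were kept in the tests.

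The table had 45101 probe sets. The 64 Affymetrix control probe sets were left out, and 45037 were tested. Gene names came from the platform annotation given with the data. In it 34945 of the tested probe sets had 1 gene symbol, 932 had several and 9160 had none. Symbols were brought up to date through the gene identifiers for 34741 probe sets, and no gene was named from a probe set with several symbols. Chromosomes and gene neighbourhoods came from the mouse reference annotation of the assembly GRCm38, and no coordinates are given because the array table states no build.

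Group means were fitted to the log2 values of all 8 arrays in 1 linear model with limma 3.58.1 in R 4.3.3, which left 5 residual degrees of freedom. The contrasts were homozygous minus wild type, heterozygous minus wild type and homozygous minus heterozygous. P-values came from limma's moderated test (eBayes, two-sided) and were adjusted by the Benjamini-Hochberg method over the 45037 probe sets, with a threshold of 0.05. Unadjusted p-values in the text are from the same test, and SE is its moderated standard error. Levels of Nxnl1 and its paralog Nxnl2 were also compared by exact two-sided permutation tests.

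Before the data were examined, 29 gene lists with 671 entries were written for retinal cell types, photoreceptor function, stress, immunity, metabolism, chromosomal neighbours of Nxnl1, sex chromosomes, the clock, and tissues that a retina dissection can carry along. Of the entries, 609 were measured. Each gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes. Lists were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted by the Benjamini-Hochberg method over the 29 lists. Camera was repeated with a correlation estimated for each list, and limma's fry tested whether the genes of a list moved, on balance, one way.

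The rule for named genes was fixed at the same time. Nxnl1 and Nxnl2 came first, followed by genes past the adjusted threshold whose groups did not overlap, up to 12 per direction. Where too few passed, the genes with the smallest unadjusted p and a log2 difference of at least 0.5 followed, up to 6 per direction for homozygous against wild type and 3 for the other comparisons. In each list up to 4 members with the smallest unadjusted p could be named. Names of uncharacterised transcripts were skipped.

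Further fits used a repeated quantile normalization, equal array medians, leaving out probe sets below the median level, an intensity trend or a robust prior in the variance model, array weights, a fit to 2 groups only, the replicate number as a block, leaving out each array in turn, a minimum fold of 1.5, an ordinary test without moderation, the mean of all probe sets of a gene and a correlation estimated for each list. Other fits, chosen after the data had been seen, left out 2 arrays whose Nxnl1 level went against their label (heterozygous array 2 and homozygous array 2), added the difference between the 5' and 3' actin control probe sets as a covariate, did both, or left out the arrays with the lowest such difference (wild-type array 1 and homozygous array 1).

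The tests were tested on simulated data drawn from the means and residual spread of the 45037 probe sets, with 200 of them changed. For homozygous against wild type, 62% of 100 probe sets changed by a log2 value of 1 and 93% of 100 changed by 2 were recovered, with 9 false calls among 164. With the 2 arrays left out, the shares were 29% and 80%. A simulated list of 30 genes shifted by 0.5 passed camera, and none of the 29 unshifted lists did. Genes were drawn independently of each other in these simulations. In the measured data, the lists that passed for homozygous against wild type had estimated correlations from 0.14 to 0.40. The simulations thus do not show how often camera calls unshifted lists whose genes move together. The recovery shares likewise hold only for arrays with no structure besides genotype.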

Results

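The study profiled the retinas of mice that lack Nxnl1, a gene expressed in photoreceptors that encodes rod-derived cone viability factor, a thioredoxin-like protein. Expression was measured for 45037 probe sets on 8 arrays: 3 labelled wild type, 2 labelled heterozygous and 3 labelled homozygous null, from retinas at postnatal day 40. Values are on the log2 scale of the deposited RMA table, so a difference of 1 is a doubling. The correlation between pairs of arrays over all probe sets ran from 0.979 to 0.996.

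Nxnl1 itself did not follow the labels on 2 arrays. Its brighter probe set read 9.22, 8.87 and 8.65 on the wild-type arrays. On the arrays labelled homozygous 1, 2 and 3 it read 6.13, 8.76 and 6.13, and on those labelled heterozygous 1 and 2 it read 8.65 and 6.75. Its second probe set had the same pattern, with 6.21, 6.76 and 6.70 in wild type, 5.47, 6.62 and 5.56 on the arrays labelled homozygous 1, 2 and 3, and 6.79 and 5.48 on those labelled heterozygous 1 and 2. The array labelled homozygous 2 thus sat at the wild-type level and the array labelled heterozygous 2 below every wild-type array, so each direction given for a genotype in the rest of the text mixes arrays whose target gene goes against the label. The array labelled heterozygous 1 was also near the wild-type level, at -0.26 and 0.23 from the wild-type mean at the brighter and second probe sets. Over the arrays as labelled, the mean of the brighter probe set was 8.91 ± 0.29 (SD, n = 3) in wild type and 7.01 ± 1.52 (SD, n = 3) in the homozygous group, a log2 difference of -1.91 with an SE of 0.73. An exact two-sided permutation test gave p = 0.2, where 3 arrays against 3 cannot go below 0.1, and the limma adjusted p was 0.9999. Without the arrays labelled heterozygous 2 and homozygous 2, the difference was -2.78 (SE 0.18, limma adjusted p 0.26). These arrays were chosen by their Nxnl1 level after the data were seen, so that choice shapes this difference and its SE, and the p tests nothing about Nxnl1.

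Nxnl2, the paralog of Nxnl1, read 11.58, 11.88 and 11.65 in wild type at its brighter probe set. It read 11.18, 11.79 and 11.19 on the arrays labelled homozygous 1, 2 and 3, and 11.60 and 11.23 on those labelled heterozygous 1 and 2. The log2 difference of homozygous against wild type was -0.32 (SE 0.19, unadjusted limma p 0.131), and the exact permutation test gave p = 0.3. Without the 2 arrays in doubt the difference was -0.52 (SE 0.13, unadjusted limma p 0.00676, adjusted p 0.976). Its dimmer probe set differed by -0.24 (SE 0.25), by -0.42 (SE 0.21) without the 2 arrays in doubt, and by -0.0032 without homozygous array 1.

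**Figure D1:**
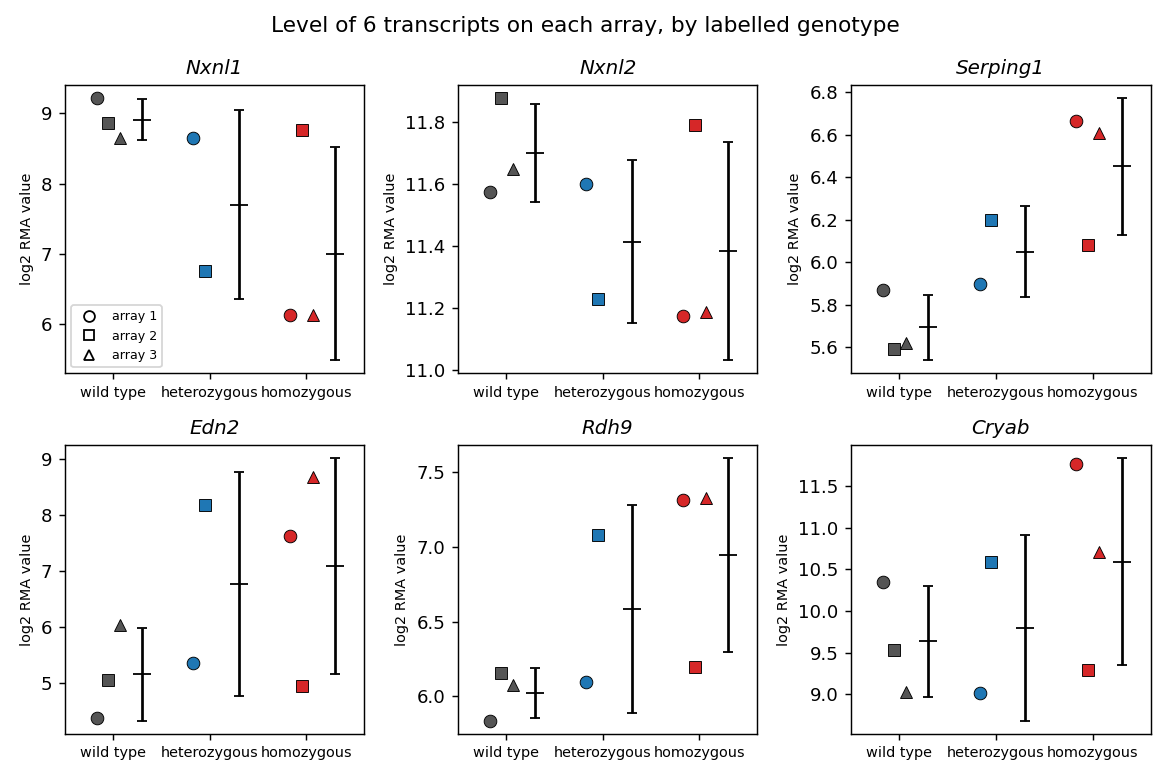
Level on the log2 RMA scale (vertical axis) of Nxnl1, Nxnl2, Serping1, Edn2, Rdh9 and Cryab on each of the 8 arrays, by labelled genotype (horizontal axis); circles, squares and triangles are arrays 1, 2 and 3 of a group, and each bar is the group mean with its SD. For Nxnl1 the array labelled homozygous 2 (8.76) lies among the wild-type arrays and the array labelled heterozygous 2 (6.75) lies below them.

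The arrays also differed in RNA quality, in sex-linked transcripts and in transcripts of neighbouring eye tissues. The 5' minus 3' difference of the actin control probe sets, which falls as RNA degrades, was -1.81, -1.04 and -0.80 in wild type, -0.90 and -0.71 in the heterozygous group and -1.74, -0.69 and -1.26 in the homozygous group. The first principal component, with 53.6% of the variance between arrays, correlated with this difference over the 8 arrays (Pearson r = 0.941, exact permutation p = 0.00437; Spearman rho = 0.857, exact permutation p = 0.0107), and r was 0.724 over the 6 arrays left without wild-type array 1 and homozygous array 1. Eif2s3y, a gene on the Y chromosome, read 3.46 and 3.32 on wild-type arrays 1 and 2 and at least 7.07 on the 6 others. Xist, transcribed from the inactive X chromosome, read at least 9.71 on all 8 arrays at 1 of its probe sets. The 6 others thus held both transcripts and cannot be put to 1 sex by them. Among them, Eif2s3y read 7.38, 7.07 and 7.77 on the arrays labelled homozygous 1, heterozygous 2 and homozygous 3, where Nxnl1 was low. It read 9.13, 9.14 and 8.73 on the arrays labelled heterozygous 1, homozygous 2 and wild type 3. Genotype and these Y-linked transcripts were therefore not balanced, with a log2 difference of homozygous against wild type of 2.92 (SE 1.36) for Eif2s3y.

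The comparison of homozygous null with wild type asks what the loss of Nxnl1 does to the retinal transcriptome. By the fixed rule, the transcripts of smallest unadjusted p with a log2 difference of at least 0.5 above wild type on the arrays labelled homozygous were Serping1, the inhibitor of complement C1, with a log2 difference of 0.76 (SE 0.17), the endothelial receptor kinase Tie1 with 0.58 (SE 0.17), Serpina1b with 0.52 (SE 0.17), the kainate receptor subunit Grik1 with 0.54 (SE 0.18), the splicing factor Son with 0.55 (SE 0.19) and the bestrophin Best2 with 0.56 (SE 0.20). Serping1 read 6.67, 6.08 and 6.61 on the arrays labelled homozygous 1, 2 and 3, all above the 3 wild-type arrays, which read 5.87, 5.59 and 5.62. Below wild type, by the same rule, were the transcription factor Sp1 with -0.61 (SE 0.18), Nxnl1, the splicing factor Srsf11 with -0.52 (SE 0.22), Mia3 with -0.56 (SE 0.24), the cytochrome c oxidase subunit Cox8b with -0.52 (SE 0.22) and Avl9 with -0.72 (SE 0.32). None of these passed the adjusted threshold. Tie1, Serpina1b and Avl9 lay near the lower end of the scale. Their means were 3.65, 4.18 and 4.31 in wild type and 4.23, 4.70 and 3.59 in the homozygous group. With 1 array left out, all 12 kept their direction and 6 moved by more than 1.5 times: Tie1 to 0.37, Srsf11 to -0.26 and Mia3 to -0.28 without homozygous array 1, Best2 to 0.31 without homozygous array 3, Cox8b to -0.29 without wild-type array 1 and Avl9 to -0.29 without wild-type array 3. Limma called 0 of 45037 probe sets, with a smallest adjusted p of 0.9999, and so did the ordinary test without moderation. At an unadjusted p under 0.05 there were 411 probe sets, 241 higher and 170 lower, against 2252 by chance alone, and the ordinary test had 801.

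With the 2 arrays in doubt left out, the same rule took the smallest unadjusted p among genes with a log2 difference of at least 0.5. Above wild type these were Rdh9, a retinol dehydrogenase, at 1.30 (SE 0.13), Lrrc2 at 1.28 (SE 0.15), Nudt6 at 1.31 (SE 0.15), Serping1 at 0.94 (SE 0.13), the matricellular protein Ccn2 at 0.73 (SE 0.10) and Sox30 at 1.40 (SE 0.19). Below it were Nxnl1, the proteoglycan Ncan at -0.60 (SE 0.13), the protein kinase Prkcb at -0.54 (SE 0.13), the caspase inhibitor Xiap at -0.73 (SE 0.17), Nxnl2 and Trip11 at -0.54 (SE 0.14). Again 0 probe sets passed the adjusted threshold, with 903 at an unadjusted p under 0.05, of which 598 were higher. Nudt6 differed at 1 of its 2 probe sets only, and the other read between 6.19 and 6.60 on all 8 arrays. Prkcb lay near the lower end of the scale, with a mean of 4.55 in wild type and 4.02 on homozygous arrays 1 and 3. The array labelled heterozygous 2 went with homozygous arrays 1 and 3 at several of these genes. Rdh9 read 7.31 and 7.33 on the arrays labelled homozygous 1 and 3, 7.08 on that labelled heterozygous 2, and between 5.84 and 6.20 on the 5 others. The brighter probe set of Nudt6 read 9.20 and 9.18 on the arrays labelled homozygous 1 and 3, 9.20 on that labelled heterozygous 2, and between 7.64 and 8.14 on the others. Of these 12 genes, the array labelled heterozygous 2 lay nearer to homozygous arrays 1 and 3 than to wild type at 9, which include Nxnl1 by the choice of arrays, and the arrays labelled heterozygous 1 and homozygous 2 at 0.

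Among the gene lists, the list of retinal stress and gliosis passed camera at the preset correlation on the arrays labelled homozygous, with 26 of 29 measured members above 0 and a median log2 difference of 0.15 (adjusted p 6.4e-05). It did not pass with an estimated correlation (adjusted p 0.838). The members of smallest p were the cytokine Lif at 0.30 (SE 0.10), the siderophore-binding Lcn2 at 0.61 (SE 0.23), the acute-phase inhibitor Serpina3n at 0.40 (SE 0.17) and the peptide Edn2 at 1.93 (SE 1.02). Edn2 was uneven within the group, reading 7.63, 4.96 and 8.68 on the arrays labelled homozygous 1, 2 and 3, 5.36 and 8.18 on those labelled heterozygous 1 and 2, and 4.38, 5.06 and 6.03 in wild type. No member passed the test, whether adjusted over all probe sets or adjusted over the list alone. Without the 2 arrays in doubt the median was 0.29 with 25 of 29 members above 0 (adjusted p 3.9e-08, and 0.902 with an estimated correlation), and 3 members passed when adjusted over the list alone, Edn2 among them (adjusted p 0.0214).

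The list of antigen presentation and the interferon response also passed at the preset correlation, with 23 of 27 members above 0 and a median of 0.12 (camera, adjusted p 7.6e-05). It did not pass with an estimated correlation (adjusted p 0.838). Without the 2 arrays in doubt the median was 0.22 with 24 of 27 members above 0 (adjusted p 2.6e-05, and 0.902 with an estimated correlation). The immunoproteasome subunit Psmb9, at 0.42 (SE 0.09), passed when adjusted over the list alone (adjusted p 0.038) and not over all probe sets, and without the 2 arrays in doubt it did not pass over the list either (adjusted p 0.0919). Irf7 at 0.26 (SE 0.10), Bst2 at 0.37 (SE 0.16) and the interferon-induced GTPase Igtp at 0.28 (SE 0.13) did not pass. Without the array labelled homozygous 1 the list's adjusted p was 0.054.

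Lists of microglia (18 of 20 members above 0, median 0.11, adjusted p 0.0238), of vascular cells (19 of 22, median 0.09, adjusted p 0.0252) and of chromosomal neighbours of Nxnl1 (32 of 41, median 0.10, adjusted p 0.0102) passed camera upward at the preset correlation, and the list of RPE and choroid genes passed downward, with 7 of 21 members above 0 and a median of -0.09 (adjusted p 0.0277). None of these 4 lists passed with an estimated correlation (adjusted p 0.838 for each). Their leading members included the macrophage lysozyme Lyz2 at 0.27 (SE 0.10), Cd68 at 0.31 (SE 0.15) and the complement genes C1qc at 0.46 (SE 0.29) and C1qa at 0.32 (SE 0.25) for microglia, and Tie1, Emcn at 0.19 (SE 0.11), Pecam1 at 0.25 (SE 0.17) and Flt1 at 0.24 (SE 0.18) for vessels. Among the neighbours they were Ifi30 at 0.28 (SE 0.10), Bst2, which the interferon list also holds, and Rab3a at 0.20 (SE 0.10). The pigment epithelium list had Dct at -0.35 (SE 0.21), the visual cycle genes Rgr at -0.37 (SE 0.24) and Rpe65 at -0.38 (SE 0.27), and Best1 at 0.16 (SE 0.09). That list was written for tissue that a retina dissection can carry along, so its direction need not be one of the retina. No member of these 4 lists passed the test.

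With 1 array left out, 89 of 112 leading members of all 29 lists moved by more than 1.5 times and 7 turned direction for homozygous against wild type, and 83 of 113 and 9 for heterozygous against wild type. None of the 6 list calls held with a correlation estimated for each list, where the adjusted p was 0.838 for all 6. By fry, which asks whether the genes of a list move one way without comparing them with other genes, the unadjusted p of these lists ran from 0.155 for interferon genes to 0.688 for RPE and choroid genes, with 0.271 for stress and gliosis. Each of the microglial, vascular, neighbour and pigment epithelium calls was lost in at least 3 of the refits that left out 1 array, and the vascular, neighbour and pigment epithelium calls were lost without the 2 arrays in doubt, at adjusted p values of 0.132, 0.0599 and 0.0599. With the actin difference as a covariate all 6 lists passed camera at the preset correlation. Leaving out wild-type array 1 and homozygous array 1, which had the lowest actin differences, lost the interferon, microglial, neighbour and vascular calls. Their camera adjusted p values were then 0.0621, 0.0595, 0.253 and 0.759. The stress and gliosis list and the RPE and choroid list still passed, at 0.00123 and 0.0246.

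The complement list did not pass (10 of 14 members above 0, adjusted p 0.0637), although Serping1 passed when adjusted over this list alone (adjusted p 0.031). The lens list, with 15 of 20 members above 0 and a median of 0.34, did not pass either (adjusted p 0.201). Its crystallin genes were uneven between arrays: Cryab read 11.76, 9.29 and 10.71 on the arrays labelled homozygous 1, 2 and 3, 9.01 and 10.59 on those labelled heterozygous 1 and 2, and 10.35, 9.53 and 9.03 in wild type. Without the 2 arrays in doubt both lists passed, at adjusted p values of 0.0223 and 0.00043, with the lens median at 0.72, and neither did with an estimated correlation (adjusted p 0.902 for each).

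None of the photoreceptor lists passed the test. For rod phototransduction 15 of 22 members were above 0 with a median of 0.02 (adjusted p 0.763), and the members of smallest p were Cngb1 at 0.13 (SE 0.11), Gngt1 at -0.13 (SE 0.11), Prph2 at -0.17 (SE 0.16) and Grk1 at -0.27 (SE 0.27). For cone photoreceptors 9 of 17 were above 0 with a median of 0.0020 (adjusted p 0.763), led by Gulo at -0.18 (SE 0.14), the short-wave cone opsin Opn1sw at 0.18 (SE 0.15), Ccdc136 at 0.11 (SE 0.10) and the cone transducin subunit Gnb3 at 0.14 (SE 0.14). Photoreceptor regulators and structural genes had 6 of 21 members above 0 and a median of -0.02 (adjusted p 0.153), and without the 2 arrays in doubt the median was -0.08 (adjusted p 0.0613). Ribbon synapse genes had 9 of 14 above 0 (adjusted p 0.777).

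Lists of the other retinal cells did not pass: bipolar cells (14 of 19 members above 0, adjusted p 0.197), Müller glia (11 of 22, 0.375), amacrine cells (16 of 19, 0.518), horizontal cells (8 of 10, 0.577), ganglion cells (10 of 18, 0.577) and astrocytes with oligodendrocytes (9 of 14, 0.526). The antioxidant and redox list had 22 of 33 members above 0 (adjusted p 0.428), led by the glutathione peroxidase Gpx3 at 0.89 (SE 0.37), which ran from 0.47 to 1.33 with 1 array left out, and the haem oxygenase Hmox1 at 0.18 (SE 0.09). Thioredoxin-like genes had 8 of 12 above 0 (adjusted p 0.375), unfolded protein and heat shock genes 12 of 23 (0.197), apoptosis genes 18 of 24 (0.458), immediate early genes 16 of 21 (0.25), clock genes 11 of 21 (0.395), glycolysis and glucose transport genes 14 of 22 (0.783) and oxidative phosphorylation genes 23 of 38 (0.829). Markers of blood (4 of 10, 0.527), of cornea, iris and ciliary body (12 of 19, 0.577) and of the sex chromosomes (5 of 10, 0.763) did not pass either. In 7 of the lists that did not pass the median lay above 0 while camera's direction was down, since camera sets a list against all other genes, whose median was 0.02.

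**Figure D2:**
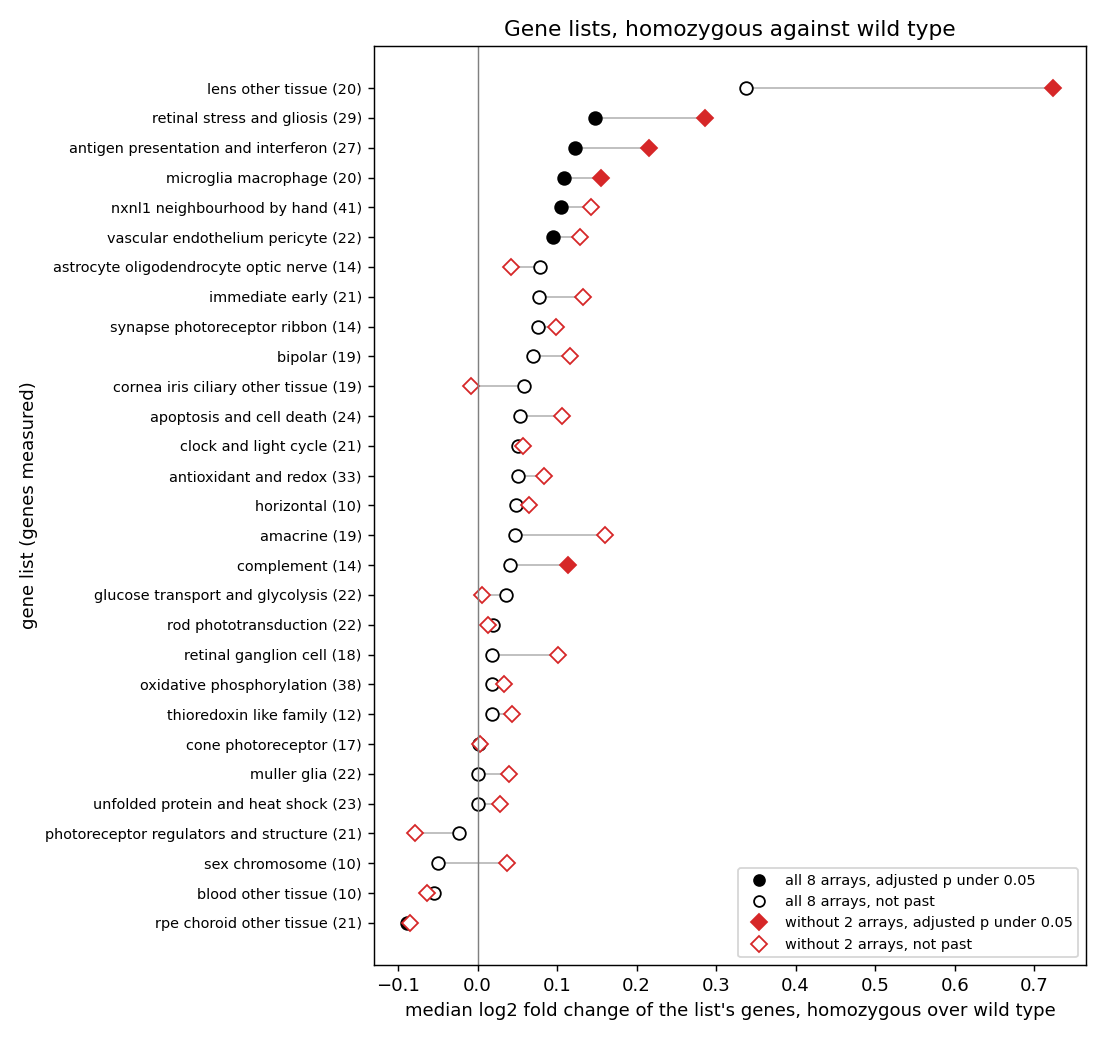
Median log2 fold change of the measured genes of each of the 29 lists, homozygous over wild type (horizontal axis), by list (vertical axis, with the number of genes measured). Black circles are the fit to all 8 arrays and red diamonds the fit without heterozygous array 2 and homozygous array 2; filled symbols have a camera adjusted p under 0.05 at the preset correlation. Retinal stress and gliosis has a median of 0.15 in the first fit and 0.29 in the second.

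The comparison of heterozygous with wild-type retinas asks for the effect of a single null allele. Among named genes with a log2 difference of at least 0.5, Prss56, a serine protease gene expressed in Müller glia, had the smallest unadjusted p. Its log2 difference was -1.04 (SE 0.17). It read 5.60 and 5.73 on the arrays labelled heterozygous 1 and 2 and at least 6.38 on the 6 others. Among genes below wild type, the scaffold genes Iqgap2 and Iqgap3 came next with -0.62 (SE 0.12) and -0.55 (SE 0.14). Above wild type were Son with 0.91 (SE 0.21), Cacng3, a subunit that accompanies AMPA receptors, with 0.59 (SE 0.20) and the metalloprotease Tll1 with 0.51 (SE 0.17). None passed the adjusted threshold. Limma called 0 probe sets, with a smallest adjusted p of 0.9999 and 516 at an unadjusted p under 0.05, of which 230 were higher, and the ordinary test also called 0, with 1236. Nxnl1 differed by -1.21 (SE 0.82) and Nxnl2 by -0.29 (SE 0.21), but the 2 heterozygous arrays were unlike. The Nxnl1 difference was -0.26 without the array labelled heterozygous 2, which is in doubt, and -2.16 without heterozygous array 1, and that of Nxnl2 was -0.10 and -0.47. These values are of the brighter probe sets. The dimmer probe sets differed by -0.42 for Nxnl1 and -0.05 for Nxnl2. Both turned direction without the array labelled heterozygous 2, to 0.23 and 0.32.

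By camera at the preset correlation, 2 of the 29 lists passed for heterozygous against wild type, and neither passed with an estimated correlation. The list of antigen presentation and interferon genes passed upward, with 21 of 27 members above 0 and a median of 0.18 (adjusted p 1.8e-08, and 0.808 with an estimated correlation). Without the array labelled heterozygous 2, which is in doubt, its median was 0.08 and its adjusted p 0.0477. The members of smallest p were Irf7 at 0.31 (SE 0.12), Iigp1 at 0.28 (SE 0.11), H2-D1 at 0.62 (SE 0.28) and Gbp3 at 0.41 (SE 0.20). The list of RPE and choroid genes passed downward, with 3 of 21 members above 0 and a median of -0.31 (adjusted p 1.5e-07, and 0.832 with an estimated correlation). Its members of smallest p were Dct at -0.80 (SE 0.24), Rgr at -0.68 (SE 0.27), Rpe65 at -0.74 (SE 0.31) and the thyroxine carrier Ttr at -0.67 (SE 0.28). Rpe65 read 9.25 and 9.52 on the arrays labelled heterozygous 1 and 2, 10.20, 10.48 and 9.69 in wild type, and 10.04, 10.01 and 9.16 on the arrays labelled homozygous 1, 2 and 3. This list was written for tissue that a retina dissection can carry along, and the RPE had been removed per the labels' protocols. A difference in carried tissue and an effect of the allele cannot be told apart here. No member of either list passed the test, whether adjusted over all probe sets or over the list alone. By fry the unadjusted p was 0.138 for the interferon list and 0.168 for the pigment epithelium list. Of the other 27 lists, the closest to the threshold was retinal stress and gliosis, with 22 of 29 members above 0 (adjusted p 0.0726). This rested on the array labelled heterozygous 2: without both arrays in doubt 11 of 29 members were above 0, the median was -0.02 and the adjusted p 0.429.

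The comparison of homozygous with heterozygous arrays asks what the loss of the other allele adds. Above the heterozygous level were Prss56 at 0.92 (SE 0.17), Spry3, an antagonist of receptor kinase signalling, at 0.54 (SE 0.14) and the receptor Gpr83 at 0.53 (SE 0.14). Below it were Tiparp at -0.75 (SE 0.26), the vesicle GTPase Rab3c at -0.87 (SE 0.32) and the transcription factor Klf6 at -0.53 (SE 0.19). Nxnl1 differed by -0.70 (SE 0.82) and Nxnl2 by -0.03 (SE 0.21), and neither kept its direction with 1 array left out. Nxnl1 ran from -1.65 without the array labelled heterozygous 2 to 0.25 without heterozygous array 1, and Nxnl2 from -0.23 to 0.16. Rab3c ran from -1.36 to -0.38 and Spry3 from 0.34 to 0.74. None of these genes passed: limma called 0 probe sets, with a smallest adjusted p of 0.99998 and 405 at an unadjusted p under 0.05, of which 242 were higher, and the ordinary test called 0, with 981.

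Across 18193 genes, which are not independent replicates, the log2 differences of heterozygous and homozygous against wild type correlated at r = 0.545, with a covariance of 0.00836. Both comparisons share the 3 wild-type arrays: 100 simulations of unchanged groups against shared controls gave a mean r of 0.445 and a mean covariance of 0.0129, so the observed covariance did not exceed that of shared controls alone. Of the 560 ways to relabel the 8 arrays, 184 gave an r as high. With the wild-type arrays divided 1 and 2 between the comparisons, r ran from -0.327 to 0.158 over the 6 ways, and without the 2 arrays in doubt it was 0.0816.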

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

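The count of 0 probe sets past the adjusted threshold held for all 3 comparisons under the other fits written beforehand, with 1 exception. Without wild-type array 3, the only wild-type array with Y-linked transcripts, 1 probe set passed both for homozygous and for heterozygous against wild type (range over arrays left out 0 to 1). That probe set has no gene named here and read 2.96 and 2.90 on wild-type arrays 1 and 2, 9.24 on wild-type array 3 and at least 8.85 on the others. Of the alternatives chosen after seeing the data, leaving out heterozygous array 2 and homozygous array 2 with the actin covariate gave 1, which was Nxnl1 at -2.91 (adjusted p 0.0236); the arrays were chosen by their Nxnl1 level, so this call tests nothing about Nxnl1. The camera call count for homozygous against wild type moved from 6 to 3 without dim probe sets, 3 without wild-type array 1 and homozygous array 1 together, and 0 with an estimated correlation. Leaving out 1 array gave 3 to 7, with 7 without wild-type array 1 and 3 without homozygous array 1 and without wild-type array 2. Retinal stress and gliosis passed in 18 of 19 alternatives, interferon genes in 16, RPE and choroid in 12, microglia and Nxnl1 neighbours in 10 and vessels in 9. For heterozygous against wild type the count moved from 2 to 5 with array weights, 4 with the mean of all probe sets, 0 with an estimated correlation, 6 without the 2 arrays in doubt, 11 with the actin covariate, 10 with both, 9 without wild-type array 1 and homozygous array 1, and 2 to 8 with 1 array left out, where it was 8 without wild-type array 1, 8 without heterozygous array 1 and 5 without heterozygous array 2. The correlation of log2 differences was 0.0182, -0.327, 0.0448, 0.158, -0.311 and -0.0045 with divided wild-type arrays, 0.0816 without the 2 arrays in doubt, and 0.313 to 0.720 with 1 array left out, lowest without heterozygous array 2 and highest without wild-type array 3. Dividing the wild-type arrays removes the part of r that shared controls give by construction, a mean of 0.445 in the simulations of unchanged groups. Whether this accounts for values as low as -0.327 and -0.311 was not tested, nor was the cause of the other moves.

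The named genes and the lists with members in the text gave 85 gene differences, none past the threshold in the main fit. They leave out Nxnl1 and Nxnl2 in the comparisons with heterozygous arrays. They also leave out the brighter Nxnl1 probe set for homozygous against wild type, which passed in 1 fit as given above. Keeping the side of the threshold was thus nearly fixed beforehand, and a difference could keep it and still move in size. Of 1479 values under alternatives, 1474 kept their direction and side of the threshold. The 5 that turned were of rod genes within their error: Cngb1 at -0.00074 with array weights, where leaving out 1 array gave 0.0238 to 0.195, Grk1 at 0.0268 without wild-type array 3, where leaving out 1 array gave -0.529 to 0.0268, and Prph2 at 0.0315 without homozygous array 2, where leaving out 1 array gave -0.296 to 0.0315, 0.0315 without both arrays in doubt and 0.0713 with the actin covariate as well. The shared replicate numbers did not show a pairing of all samples. Deviations from the group means correlated at 0.616, 0.230 and -0.03 between wild-type and homozygous arrays 1, 2 and 3. Of 3 wild-type arrays, 1 correlated best with its own number. These 3 pairs are too few to exclude a pairing, and wild-type and homozygous arrays 1 also shared the lowest actin differences. With the replicate block the counts of probe sets stayed at 0, 0 and 0, and the Nxnl1 difference at -1.91. The robust prior was not run for the lists, since camera has no such option. Where a left-out array leaves 1 heterozygous array, its spread is taken to be that of the other groups.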

Other observations

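All tests of an explanation in this part were chosen after the result was seen. An exchange of the labels of heterozygous array 2 and homozygous array 2 would put each at the level of the other's group. On 200 probe sets chosen without both arrays and without Nxnl1, with 0 the wild-type mean and 1 the mean of homozygous arrays 1 and 3, the median position was 0.59 for the array labelled heterozygous 2 (quartiles 0.28 and 0.90) and -0.07 for that labelled homozygous 2 (quartiles -0.30 and 0.17). The difference of 0.657 was larger than in the 9 other divisions of the same 5 arrays, which reached at most 0.444 in size. These divisions are too few for a share under 0.05. Heterozygous array 1 lay at 0.16 (quartiles -0.04 and 0.46). The array labelled heterozygous 2 was past the midpoint at 56% of the probe sets. The probe sets were chosen for their difference between homozygous arrays 1 and 3 and wild type. A held-out array is therefore expected to fall short of 1, even if it belongs with homozygous arrays 1 and 3. The position of 0.59 thus cannot show whether the array labelled heterozygous 2 lay between the groups. An exchange of its label with that of homozygous array 2 may account for the pattern and is not shown by these values. After such an exchange both heterozygous arrays would read Nxnl1 near the wild-type level. RNA degradation was argued against, because the actin differences of both arrays were 0.0114 apart while their Nxnl1 levels were 2.01 apart, as were probe sets outside the lost part of the transcript, because the smaller fall on homozygous arrays 1 and 3 was -1.04. Separate labelling or genotyping errors stay open, and so does a part for lens or stressed tissue in the 200 probe sets. Variation between heterozygous samples stays open only for the array labelled heterozygous 2. It cannot account for the array labelled homozygous 2, whose 2 Nxnl1 probe sets were -0.15 and 0.06 from the wild-type mean.

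Crystallin transcripts were high on the arrays labelled homozygous 1 and 3, where the median of 8 alpha and beta crystallins was 10.43 and 8.93, and also on wild-type array 1 (9.17) and the array labelled heterozygous 2 (9.10), against 5.87 to 6.88 on the others. Lens carried into the dissection could bring them. Gamma crystallins, abundant in lens fibres, did not follow in proportion: 4 of them minus the alpha and beta median was 0.83 on wild-type array 1 and at most -2.62 on homozygous arrays 1 and 3, a gap of 3.45. Their median was 7.81 on homozygous array 1 and 5.86 on homozygous array 3, against 5.42 and 4.54 on wild-type arrays 2 and 3. The lens membrane gene Mip read between 4.82 and 5.17 on all 8 arrays. Mip was thus flat even on wild-type array 1, where gamma crystallins were highest, so its level cannot decide on a lens origin. Lim2, also a lens membrane gene, read 5.71 on wild-type array 1 and 5.58 on homozygous array 1. It read between 4.98 and 5.21 on the others, which include homozygous array 3 and the array labelled heterozygous 2. A lens origin and crystallin expression in the retina cannot be told apart here, because the makeup of any carried tissue is unknown, and a biological origin was not tested.

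The list of chromosomal neighbours of Nxnl1, written by hand, passed upward in the homozygous comparison at the preset correlation only (adjusted p 0.838 with an estimated one, and 0.0599 without the 2 arrays in doubt), and a flanking chromosome segment from another strain is a candidate explanation. Of 164 genes within 10 Mb of Nxnl1, 3.66% had an unadjusted p under 0.05 without the 2 arrays in doubt, against a median of 4.27% in 2000 random sets matched on level (percentile 34.0). The median log2 difference of the same genes over all arrays was 0.06, at percentile 99.1 of the random sets. A segment is neither shown nor excluded by these values, since few genes near a segment need differ in level.

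With 3 arrays against 3 there are 10 divisions of the 6 arrays, too few for a share under 0.05. For homozygous against wild type, 10 of 10 gave at least the real 0 probe sets past the threshold, which a count of 0 fixes beforehand and which therefore tests nothing (highest other 12). Of the same divisions, 10 of 10 gave at least the real 411 at an unadjusted p under 0.05 (highest other 10061), and 6 of 10 at least the real 6 gene lists (highest other 11). The division with 12 and 10061 sets wild-type array 1 with homozygous arrays 1 and 3, the 3 arrays with the lowest actin 5' minus 3' differences, and so points to a structure of the samples other than genotype.

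Among the 200 genes of smallest p without the 2 arrays in doubt, 14 lay on chromosome 16 where 6.59 were expected (unadjusted p 0.00665, adjusted p 0.133 over 20 chromosomes), and 29 neighbouring pairs lay within 1 Mb where random sets had 27.3.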
